A study of Mus musculus with 5 samples.

How the data were processed

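Single-cell RNA libraries of 5 samples were made with the 10x Genomics Chromium 3′ kit, version 3, and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The 2 mesoderm samples were sorted on the green label after trypsin and EDTA, while the 3 structures were taken from pooled embryos, separated with pancreatic enzymes and trypsin, dissected, and dissociated with Accutase and trypsin, per the labels' protocols. Sorted and dissected samples therefore differ in day, gate and dissociation, and are set side by side without a direct contrast. The exception is the cells with nearly no mitochondrial UMIs, where these differences stay within the comparison. Cell Ranger 2.1.0, Seurat 3.0 and the mouse build mm10 are named in the submitters' processing notes; the role of each was not given. The labels name version 3 of the kit, and whether Cell Ranger 2.1.0 was the version run on it is unsure. The filters on cells, the treatment of doublets and any correction between the amnion libraries are not given in the sources used here.

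The deposited tables hold 1 row per retained cell. Per the file headers, the authors give raw counts of UMIs and of detected genes for each cell, which are whole numbers without normalization. Per the file headers, the authors also give the percent of a cell's UMIs that map to mitochondrial and to ribosomal genes; the gene lists behind these percentages are not given in the sources used here. Each table carries the authors' cluster numbers, a class name per cluster and UMAP positions, made separately for each table. The resolution named in the headers was 0.5 for embryonic mesoderm and allantois, 0.3 for amnion and chorion, and 0.2 for extra-embryonic mesoderm. In all 5 tables each cluster carried exactly 1 class name, giving 26 classes in total. The amnion table marks the library of each cell, and these libraries are called library 1 and library 2 after the numbers in the table. Values per gene and cell cycle phases were not analysed here, so the class names could not be checked against marker genes, and no gene is named as a result.

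Each group has 1 sample, and the amnion sample joins 2 libraries that the submitters call replicates; a test across libraries would rest on 1 residual degree of freedom and was not made. No p-value, standard error or count of changed features was computed from cells. Before the data were examined it was decided to compare embryonic with extra-embryonic mesoderm, and amnion, chorion and allantois among one another; to report every class that holds 1% or more of any sample, which all 26 classes do; and to give shares with exact Clopper-Pearson intervals at 95%. A count of 0 is reported with the share that 3 counts would give. For the amnion, the mean and SD over its 2 libraries are given beside the joined value, with each library weighted alike. Nothing in the labels says whether these libraries came from separate pools of embryos. Sums over classes, the limit of 1% mitochondrial UMIs and all comparisons of ribosomal shares were chosen after the data had been seen.

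To compare classes at different depths, genes detected (natural log) and the ribosomal share were each fitted within a library as a polynomial of degree 2 in log UMIs, leaving out cells under 1% mitochondrial, and the median departure of each class with at least 10 cells was taken. Mixing of the amnion libraries was measured as the share of the 15 nearest neighbours of a cell, within its class in the deposited UMAP layout, that belong to the other library, divided by the share that random mixing gives. The steps were tested on simulated data: at least 95% of intervals held the true share, shuffled libraries gave a mixing ratio of 0.96 and libraries set apart gave 0, and a class offset of -2 percentage points was recovered as -1.92. The offset was put on cells drawn without regard to their UMI totals, so a class that differs in depth from its library was not simulated. Counts could not be thinned to a common depth from per-cell totals, so shares were also recomputed over the cells in the UMI range that all 5 tables share, from the highest 5th to the lowest 95th percentile (18094 to 21977 UMIs).

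Other alternatives left out the 5% of cells with the most UMIs in each table as possible doublets, cells with 5% or more mitochondrial UMIs, cells with fewer than 2000 genes, each amnion library in turn and, added after the data had been seen, cells under 1% mitochondrial. A share counted as moved when it left its own 95% interval, a median when it left the binomial order-statistic interval of the median, and an amnion value when it moved by more than the SD of its libraries. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.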

Results

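The transcriptomes of 8074 single cells from gastrulating mouse embryos of the CD1 strain were described by a table of cells for each of 5 samples. The embryos carried T-Cre with the mTmG reporter, in which cells descended from Brachyury (T) expressing cells, chiefly those that pass through the primitive streak, switch from a red to a green membrane label. At embryonic day E7.25, green cells were sorted from the embryonic region (embryonic mesoderm, 2496 cells) and from the extra-embryonic region (extra-embryonic mesoderm, 888 cells). At E7.5, 3 extra-embryonic structures were dissected by hand and sequenced without a sort: the amnion (756 cells), the membrane that encloses the embryo; the chorion (3071 cells), a contributor to the placenta; and the allantois (863 cells), the bud that gives rise to umbilical vessels. Each sample was 1 library, except the amnion, whose table joined library 1 with 277 cells and library 2 with 479 cells. The submitters describe the amnion as having 2 replicates and every other sample as having 1. No test between groups was made, because any spread between libraries would come from the amnion pair alone, and intervals on shares of cells are exact binomial (Clopper-Pearson, 95%) and cover counting error only.

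The depth per cell differed between samples. The median cell held 14017 unique molecular identifiers (UMIs, counted RNA molecules) in embryonic mesoderm, 28379 in extra-embryonic mesoderm, 39027.5 in amnion, 13577 in chorion and 26349 in allantois. The median cell showed 3344.5 detected genes in embryonic mesoderm, 4585.5 in extra-embryonic mesoderm, 5432.5 in amnion, 3302 in chorion and 4766 in allantois. The retained cells together held 36614517 UMIs in embryonic mesoderm, 25860278 in extra-embryonic mesoderm, 33139808 in amnion, 49943834 in chorion and 24550190 in allantois. The lowest UMI total of any cell was 8007 in embryonic mesoderm, 15006 in extra-embryonic mesoderm, 8117 in amnion, 7502 in chorion and 7662 in allantois, so the tables do not reach down to the same depth. The median mitochondrial share of UMIs lay between 2.04% in amnion and 2.34% in chorion.

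The first comparison set the mesoderm of the embryonic region beside that of the extra-embryonic region on the same day and after the same kind of sort. The authors' annotation divided the embryonic cells into 6 classes that run from the streak to regional mesoderm, while the extra-embryonic cells fell into 3 classes. In embryonic mesoderm, Cranial and Heart Mesoderm, the source of head mesenchyme and the heart, comprised 616 of 2496 cells (24.7%, 23.0 to 26.4%). Nascent Mesoderm, the cells that have just left the streak, comprised 581 cells (23.3%, 21.6 to 25.0%), with an overlapping interval. Primitive Streak cells, at the site where epiblast cells ingress, made up 18.3% (458 cells, 16.8 to 19.9%), and Lateral Plate and Paraxial Mesoderm, which forms the body wall and somites among other tissues, made up 16.9% (421 cells, 15.4 to 18.4%). Node Precursors, which relate to the organiser at the tip of the streak, were the rarest class with 34 cells (1.36%, 0.945 to 1.90%), and 0.694% (0.0842 to 2.49%) of the 288 embryonic cells in the UMI range that all 5 tables share, 18094 to 21977 UMIs. In that range the 4 larger classes could not be put in order: Lateral Plate and Paraxial Mesoderm made up 22.9% (18.2 to 28.2%), Primitive Streak 22.6% (17.9 to 27.8%), Cranial and Heart Mesoderm 21.9% (17.2 to 27.1%) and Nascent Mesoderm 20.1% (15.7 to 25.2%). The range lies above the upper quartile of embryonic cells (16773.8 UMIs), so it holds only deep cells of that sample.

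In extra-embryonic mesoderm, Nascent Mesoderm was the most frequent class with 384 of 888 cells (43.2%, 40.0 to 46.6%). Mesenchyme, loose connective cells of the extra-embryonic region, accounted for 270 cells (30.4%, 27.4 to 33.5%). Endothelial and Erythroid Progenitors, the precursors of vessels and of primitive red cells, accounted for 234 cells (26.4%, 23.5 to 29.4%). No class of embryonic mesoderm was named for blood or endothelium; 0 of 2496 cells allows a share of up to 0.120% for such a label, although cells of that kind can also lie within a class of another name. Conversely, 386 cells sorted from the embryonic region were annotated as extra-embryonic (ExE) Mesoderm, a share of 15.5% (14.1 to 16.9%).

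Nascent Mesoderm therefore took 23.3% of the cells in the embryonic table and 43.2% in the extra-embryonic table, with intervals that do not overlap. The clusters were made separately in each table, at a resolution of 0.5 for embryonic and 0.2 for extra-embryonic cells, so the shared name does not stand for 1 definition and the number of classes is partly set by the resolution. The median UMI count was 2.02 times as high in the extra-embryonic library. Its retained cells spanned 15006 to 49886 UMIs, and those of the embryonic library 8007 to 29927. The lowest extra-embryonic cell thus lay above the embryonic median of 14017. The filters on cells are not known, so their part in this ratio cannot be told. Within the shared UMI range, Nascent Mesoderm made up 46.1% of 76 extra-embryonic cells (34.5 to 57.9%) and 20.1% of 288 embryonic cells (15.7 to 25.2%). Those intervals do not overlap either. Endothelial and Erythroid Progenitors made up 14.5% of the same 76 extra-embryonic cells (7.45 to 24.4%). That share lies below the interval of the full table (23.5 to 29.4%), although the 2 intervals overlap. The range lies below the lower quartile of extra-embryonic cells (24478.8 UMIs) and above the upper quartile of embryonic cells (16773.8 UMIs).

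**Figure D1:**
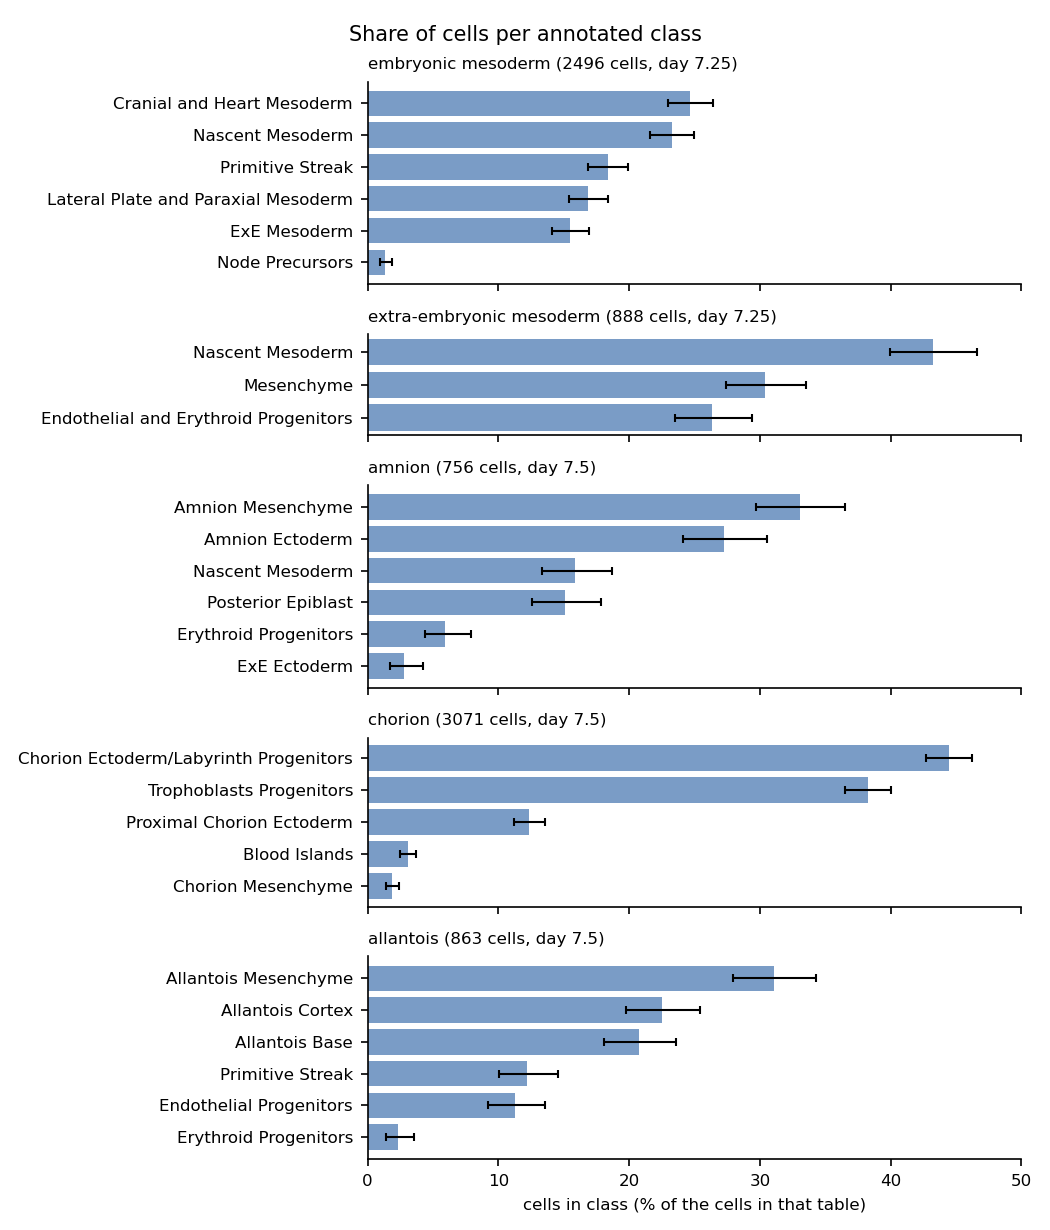
Horizontal bars give the share of cells (x axis, % of the cells in each table) in every class of the authors' annotation (y axis) for the 5 tables, with exact 95% binomial intervals as error bars. Nascent Mesoderm reaches 43.2% in extra-embryonic and 23.3% in embryonic mesoderm, and the 3 leading chorion classes are all ectodermal or trophoblast classes.

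The second comparison concerned the cellular makeup of the 3 dissected structures at E7.5. The chorion was nearly all ectoderm and trophoblast, the largest classes of the joined amnion table were mesenchyme (33.1%) and ectoderm (27.2%), and no allantois class was named for ectoderm. In the chorion, Chorion Ectoderm/Labyrinth Progenitors, which contribute to the exchange layer of the placenta, comprised 1365 of 3071 cells (44.4%, 42.7 to 46.2%). Trophoblasts Progenitors comprised 1175 cells (38.3%, 36.5 to 40.0%) and Proximal Chorion Ectoderm 380 cells (12.4%, 11.2 to 13.6%). Ectoderm and trophoblast classes thus added up to 2920 cells (95.1%, 94.3 to 95.8%), and Chorion Mesenchyme to 57 cells (1.86%, 1.41 to 2.40%). Chorion Mesenchyme cells were also the shallowest class of that library, with a median of 9232 UMIs against 13253 in Chorion Ectoderm/Labyrinth Progenitors, and they made up 0.322% (0.00814 to 1.78%) of the 311 chorion cells in the UMI range that all 5 tables share.

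In the allantois, Allantois Mesenchyme was the most frequent class with 268 of 863 cells (31.1%, 28.0 to 34.3%). Allantois Cortex made up 194 cells (22.5%, 19.7 to 25.4%) and Allantois Base 179 cells (20.7%, 18.1 to 23.6%). A further 105 cells carried the name Primitive Streak (12.2%, 10.1 to 14.5%), and 97 were Endothelial Progenitors (11.2%, 9.21 to 13.5%). Erythroid Progenitors were the rarest allantois class with 20 cells (2.32%, 1.42 to 3.56%). In the UMI range that all 5 tables share, Erythroid Progenitors were 0 of 105 allantois cells, which allows a share of up to 2.86%, and the intervals of Allantois Base (25.7%, 17.7 to 35.2%) and Allantois Cortex (19.0%, 12.04 to 27.87%) overlapped, as in the full table. Allantois Mesenchyme made up 31.4% there (22.7 to 41.2%). Its interval overlapped those of Allantois Base and Allantois Cortex, which it does not in the full table.

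In the joined amnion table, Amnion Mesenchyme made up 33.1% of 756 cells and Amnion Ectoderm, the epithelial layer that faces the embryo, 27.2%. Nascent Mesoderm made up 15.9%, Posterior Epiblast 15.1%, Erythroid Progenitors 5.95% and ExE Ectoderm, the tissue of trophoblast origin that adjoins the epiblast, 2.78%. These joined shares hid a difference between the 2 libraries that far exceeded counting error. All 114 Posterior Epiblast cells came from library 1, where they were the largest class (41.2%, 35.3 to 47.2%); the 0 of 479 cells in library 2 allows a share of up to 0.626%. All 21 ExE Ectoderm cells also came from library 1 (7.58% of its cells). Nascent Mesoderm showed the opposite pattern, with 5 of 277 cells in library 1 (1.81%) and 115 of 479 in library 2 (24.0%).

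The remaining amnion classes were present in both libraries. Averaged over the libraries, Amnion Mesenchyme was 31.5% ± 8.30 (SD, n = 2), Amnion Ectoderm 25.5% ± 9.46 (SD, n = 2) and Erythroid Progenitors 5.76% ± 1.00 (SD, n = 2). Posterior Epiblast averaged 20.6% ± 29.1 (SD, n = 2) and Nascent Mesoderm 12.9% ± 15.7 (SD, n = 2), the SD exceeding the mean in both. The median UMI count was 45195 in library 1 and 35486 in library 2. In the UMI range shared by all 5 tables, which holds 34 amnion cells, Amnion Mesenchyme made up 5.88% (0.720 to 19.7%) and Amnion Ectoderm 67.6% (49.5 to 82.6%), which turned the order of these classes.

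**Figure D2:**
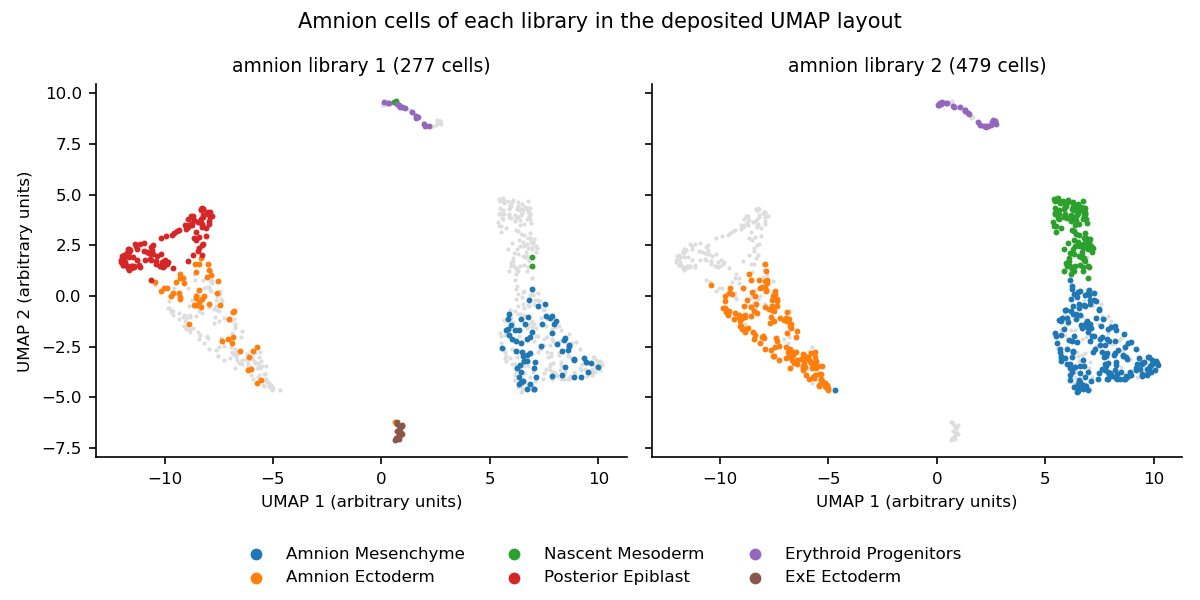
Each point is an amnion cell at its position in the deposited UMAP layout (both axes in arbitrary units), coloured by the authors' class, with library 1 on the left, library 2 on the right and the cells of both libraries in grey behind. The 114 Posterior Epiblast and 21 ExE Ectoderm cells are all in library 1, and 115 of the 120 Nascent Mesoderm cells are in library 2.

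Classes named for endothelium, red cells or blood islands, summed after the class names had been seen, were annotated in all 4 extra-embryonic samples. They made up 26.4% of the sorted extra-embryonic mesoderm, 13.6% of the allantois (117 cells, 11.3 to 16.0%), 5.95% of the amnion (45 cells, 4.37 to 7.88%) and 3.06% of the chorion (94 cells, 2.48 to 3.73%). Among the 3 dissected structures, the intervals do not overlap when the amnion is taken as 1 table. The interval of amnion library 1, however, overlaps that of the chorion. The order of allantois and amnion depends on the pooling. The allantois sum holds 97 Endothelial and 20 Erythroid Progenitors, and all 45 amnion cells are Erythroid Progenitors. No amnion or chorion class was named for endothelium. Erythroid Progenitors alone were 2.32% of the allantois (1.42 to 3.56%) and 5.95% of the amnion (4.37 to 7.88%). For these, the interval of amnion library 1 (2.79 to 8.33%) overlaps that of the allantois. The extra-embryonic mesoderm was sorted on the green label and taken at E7.25, a gate and a stage that do not apply to the dissected structures. Within the UMI range that all 5 tables share, these classes made up 14.5% of 76 extra-embryonic mesoderm, 13.3% of 105 allantois (7.49 to 21.4%), 2.94% of 34 amnion (0.0744 to 15.3%) and 0.322% of 311 chorion cells (0.00814 to 1.78%); there the amnion's interval overlaps those of allantois and chorion. In the amnion they were 5.05% of library 1 (2.79 to 8.33%) and 6.47% of library 2 (4.44 to 9.06%). In the chorion, Blood Islands cells had a lower median UMI count (10879) than the table as a whole (13577).

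A small population of cells with nearly no mitochondrial UMIs accompanied some of these samples. Over all 5 tables, 191 cells had under 0.5% mitochondrial UMIs and only 3 lay between 0.5% and 1%. Cells under 1% made up 11.0% of the allantois (95 cells, 9.0 to 13.3%), 7.22% of amnion library 1 (20 cells, 4.47 to 10.9%) and 12.5% of amnion library 2 (60 cells, 9.70 to 15.8%). They were 0.20% of embryonic mesoderm, 0.676% of extra-embryonic mesoderm and 0.261% of chorion cells. In amnion library 2 they were 21.7% of Nascent Mesoderm (14.6 to 30.4%), 16.1% of the 31 Erythroid Progenitors (5.45 to 33.7%), 14.3% of Amnion Ectoderm (9.17 to 20.8%) and 4.47% of Amnion Mesenchyme (1.95 to 8.62%). In amnion library 1 they were 17.3% of Amnion Ectoderm (8.23 to 30.3%), 7.02% of Posterior Epiblast (3.08 to 13.4%) and 0 of 71 Amnion Mesenchyme cells. The last allows a share of up to 4.23%, or 5.06% by the exact interval, which overlaps that of library 2. The 5 Nascent Mesoderm cells of library 1 are too few for a share. Within the allantois they ranged from 5.71% of Primitive Streak cells to 15.5% of Allantois Cortex cells.

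**Figure D3:**
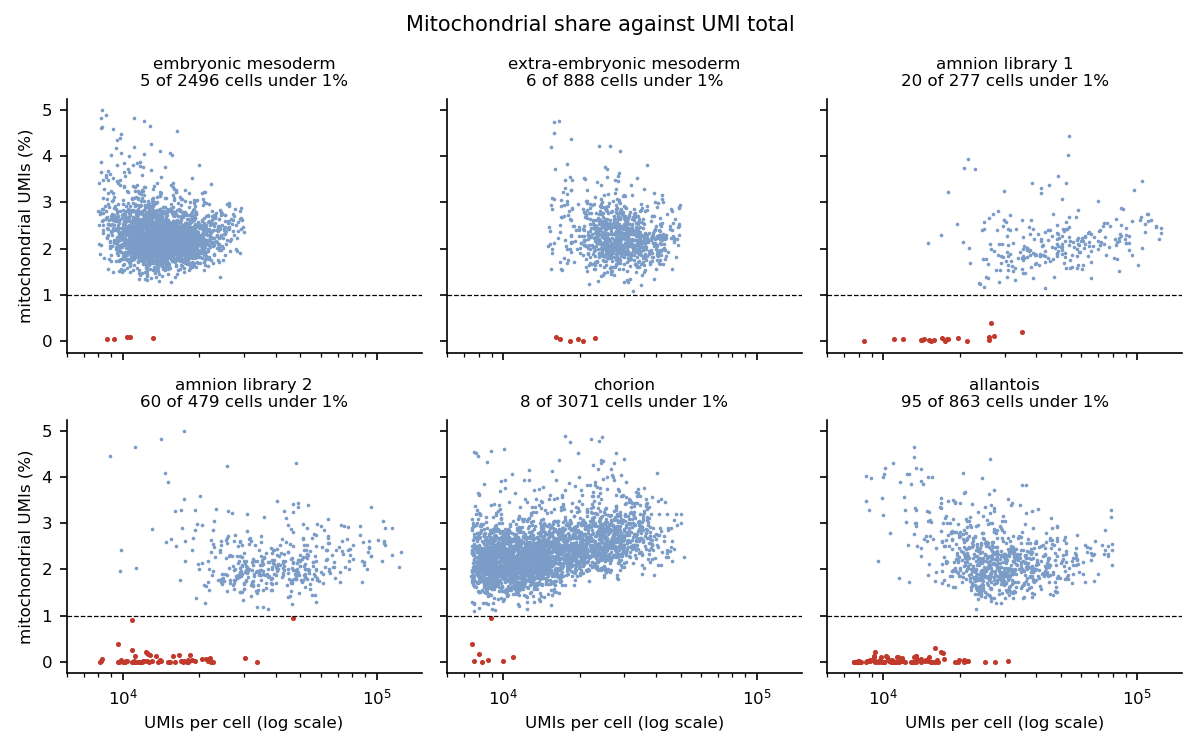
Each point is a cell, with its UMI total on a log x axis and the mitochondrial share of its UMIs (%) on the y axis, in 6 panels for the 6 libraries; red points lie under the dashed line at 1%. The red cells number 95 of 863 in allantois and 60 of 479 in amnion library 2, and 8 of 3071 in chorion.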

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

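The tests in this part were chosen after the pattern had been seen. Cells with under 1% mitochondrial UMIs exceeded the 3 counts that a count of 0 allows in every table, at 0.20% of embryonic mesoderm, 0.676% of extra-embryonic mesoderm, 10.6% of amnion, 0.261% of chorion and 11.0% of allantois cells. They are counted in the class shares and medians of the design, but no comparison of the design examines them apart. In the allantois these cells held a median of 11039 UMIs against 27672.5 in the other cells, and 2653 against 4867 detected genes.

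Chance at low depth is argued against, because the median mitochondrial share of their library predicts at least 168 mitochondrial UMIs in each such cell of allantois and amnion, whereas the median count was 1 in allantois, 4.5 in amnion library 1 and 3 in amnion library 2. Free nuclei should be poor in the cytoplasmic mRNAs of ribosomal proteins. The median ribosomal share of the low-mitochondrial cells was higher than that of the others by at least 4.52 percentage points in each of the 3 libraries (30.6% against 25.6% in allantois). This does not decide on free nuclei, because the medians were not adjusted for the lower UMI totals of these cells. The gene list behind the ribosomal percentage is also not known here. Whether UMI floors close to the median removed such cells from the other tables cannot be told apart from a real difference between samples. The 2 sorted samples also differ from the dissected ones in day, gate and dissociation. With the floors of the embryonic, extra-embryonic and chorion tables, taken relative to the median, the fraction fell to at most 0.289 of its deposited size in allantois and both amnion libraries, but this follows from the low UMI totals of these cells, and 2.70% (1.66 to 4.14%) in allantois, 0.847% (0.103 to 3.03%) in amnion library 1 and 1.79% (0.721 to 3.64%) in amnion library 2 remained under the chorion's floor, beside 0.261% (0.113 to 0.513%) in the chorion. In the range of 18094 to 21977 UMIs, which all 5 tables share, such cells were 10 of 34 in amnion and 7 of 105 in allantois against 3 of 76 in extra-embryonic mesoderm, 0 of 288 in embryonic mesoderm and 0 of 311 in chorion; the extra-embryonic share (3.95%, 0.822 to 11.1%) overlaps that of allantois (6.67%, 2.72 to 13.3%), and that range lies below the median of amnion and allantois and above that of chorion. Damaged cells that lost their mitochondria and a cell state with few mitochondrial transcripts remain untested, since values per gene were not analysed here.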

How the results depend on the processing

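Among the cells in the UMI range that all 5 tables share (288 embryonic, 76 extra-embryonic, 34 amnion, 311 chorion and 105 allantois cells), Cranial and Heart Mesoderm was 21.9% and Nascent Mesoderm 20.1% of embryonic mesoderm, beside Lateral Plate and Paraxial Mesoderm at 22.9% and Primitive Streak at 22.6% with overlapping intervals, and Amnion Mesenchyme was 5.88% of amnion. Endothelial, erythroid or blood island classes there made up 14.5% of extra-embryonic mesoderm, 2.94% of amnion and 0.322% of chorion, and ectoderm or trophoblast classes 67.6% of amnion and 99.4% of chorion. The median mitochondrial share there was 2.21% in embryonic mesoderm, 2.28% in extra-embryonic mesoderm, 1.86% in amnion, 2.45% in chorion and 2.32% in allantois. The amnion values rest on 34 cells, 10 of them under 1% mitochondrial, from the low end of that table's depth. The range lies above the upper quartile of embryonic cells (16773.8 UMIs) and below the lower quartile of extra-embryonic cells (24478.8 UMIs). This alternative moved more results than any other. It moved 13 of 18 results on the mitochondrial median, each table's largest class, Nascent Mesoderm and the sums over classes. Of the other shares, 20 of 24 moved. The cause of any difference from the full tables was not tested, in the amnion or elsewhere.

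Without the 5% of cells with the most UMIs, the median UMI count was 13863 in embryonic mesoderm and 13151 in chorion, and the median genes detected 3318 and 3244, as removing the deepest cells lowers these medians; the chorion's median mitochondrial share was 2.32%, and the cause was not tested. Without cells under 1% mitochondrial, an alternative chosen after the data were seen, the allantois medians were 27672.5 UMIs, 4867 genes and 2.19% mitochondrial, and the amnion's mitochondrial median was 2.11%. The amnion medians of 42479.5 UMIs and 5604.5 genes, against 39027.5 and 5432.5 with these cells, left their order-statistic intervals. They are not counted as moved only because amnion values are judged by the SD of the 2 libraries. No class share left its interval. The limit of 5% mitochondrial removed no cell and the minimum of 2000 genes removed 1, so neither tests anything. The other deposited clustering column equals the cluster numbers in all 5 tables, and the alternatives on cell cycle phase were not run. With 1 amnion library left out, Posterior Epiblast was 0% or 41.2%, ExE Ectoderm 0% or 7.58% and Nascent Mesoderm 1.81% or 24.0%; these are not counted as moved only because, with 277 and 479 cells, the joined share cannot differ from that of either library by more than their SD. The number of cells limits rare classes: the intervals of the 20 Erythroid Progenitors of the allantois and of the 34 Node Precursors span a factor of more than 2.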

Other observations

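The tests in this part were chosen after the patterns had been seen. Classes named for red cells or blood islands, and 1 other class, showed at least 2% fewer detected genes than the trend of their library at equal UMI totals. The median departure from the library's trend was -6.05% in Blood Islands of the chorion (91 cells), -4.65% in Erythroid Progenitors of the allantois (18 cells), -4.14% and -6.96% in those of amnion libraries 1 and 2 (14 and 26 cells), and -2.05% in Endothelial and Erythroid Progenitors of extra-embryonic mesoderm (232 cells). Endothelial Progenitors of the allantois, annotated apart from its erythroid cells, lay at -0.91% (88 cells). The drop was not particular to these, since ExE Ectoderm of amnion library 1 lay at -2.18% (19 cells). Node Precursors departed in the other direction, with 6.47% more genes than the trend of embryonic mesoderm (34 cells, interquartile range over cells 3.82 to 10.1%), and Chorion Mesenchyme stood at 2.96% (56 cells). These are medians over cells of single libraries, without a test.

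Cells under 1% mitochondrial were left out of this comparison. The ribosomal share of UMIs was lower in classes named mesenchyme than in the other cells of the same library in 5 of 5 libraries. After the trend on UMIs was removed as well, the difference was -0.61 percentage points in extra-embryonic mesoderm and -1.10 in allantois. It was -1.43 and -1.21 in amnion libraries 1 and 2, and -3.97 in chorion. Depth and the low-mitochondrial cells are therefore argued against as the whole cause, as the smallest drop that remained was -0.61. Mesenchyme was not the lowest class in extra-embryonic mesoderm, where Endothelial and Erythroid Progenitors lay at -0.74. Other classes had drops of like size, namely Node Precursors (-1.25) and ExE Mesoderm (-0.74) of embryonic mesoderm and Endothelial Progenitors of the allantois (-0.60). In the allantois the departure from the trend was 1.20 percentage points in Primitive Streak, 0.98 in Erythroid Progenitors, 0.63 in Allantois Base, -0.34 in Allantois Cortex, -0.54 in Endothelial Progenitors and -0.85 in Allantois Mesenchyme. No biological explanation was tested, and the gene list behind the percentage is not known here.

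The split of amnion classes between its 2 libraries was weighed against depth, a shift between libraries and the dissection. Within the UMI range that both libraries share (17949 to 86099), Posterior Epiblast was 43.1% of library 1 (36.6 to 49.7%). In library 2 it was 0 of 391 cells, which allows up to 0.767%. The split was present within that range as well. The range kept 232 cells of library 1 and 391 of library 2, so cells were not matched closely on depth. Whether depth shaped the classes is not decided by this, because library 2 holds none of these cells at any UMI total, so no range could change its 0. A shift of all cells between the libraries stays open: the 3 classes with at least 10 cells in each library had between 0.814 (Amnion Ectoderm) and 0.959 (Amnion Mesenchyme) of the cross-library neighbours that random mixing gives, but the layout may have been corrected between libraries before deposit. Different neighbouring tissue taken in by the dissections cannot be told apart from a difference in stage or position between the embryos used, which is untested. Over all 4 classes that both libraries hold, the largest difference in share was 20.5 percentage points, for Nascent Mesoderm (3.52%, 1.153 to 8.026%, against 24.0%, 20.2 to 28.1%), whose intervals do not overlap. Taken as shares of their own sum, the 3 classes with at least 10 cells in each library differed by at most 4.35 points, with overlapping intervals, but that minimum leaves out Nascent Mesoderm because of the split itself. Nascent Mesoderm can also be neighbouring tissue, so its difference does not exclude the explanation either.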
